A study of Caenorhabditis elegans with 6 samples.

How the data were processed

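RNA from dissected gonads of Caenorhabditis elegans young adults was sequenced in 6 samples, 3 wild-type and 3 carrying the sin-3 allele tm1276. Per the labels' protocols, gonads of 5 to 7 animals, taken 12 h after the L4 larval stage, were cut at the bend and the distal arm was kept, which holds mitotic and early meiotic germ cells together with the somatic cells around them. Libraries were made from total RNA with a stranded kit that depletes ribosomal RNA, and reads were single-end of 50 bases. The labels do not say whether the 3 samples of a genotype came from separate cultures, so p-values measure the spread between these samples, which may in part be technical.

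The count of reads per gene in each library is the one the authors deposited, whole numbers with no normalization. Per the submitters' processing notes the tools were fastp 0.20.1, STAR 2.7.3a, HTSeq 0.7.2 and DESeq2 1.36.0, listed with no role. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Neither is the aligner's handling of reads with several alignments. The count tables hold reads with several alignments and reads over several genes in lines apart from the genes. The authors also deposited a table of their own comparison, which holds log2 fold changes, their standard errors and p-values, raw and adjusted, per the file headers. 1 column of that table was not used, and 3 of its lines are totals of unassigned reads that had been treated as genes, so these were left out.

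Lines of the count tables that name no gene were kept out of library sizes and tests. They held 10.4% ± 0.84 (SD, n = 3) of all counted reads in wild type and 8.98% ± 0.24 (SD, n = 3) in the mutant. The gene-assigned total ranged from 24491014 to 30634455 reads per library. A gene with 0 counts in a library is compatible with a level of up to 3 counts, or 0.0942 to 0.130 CPM (counts scaled to a common library size), and this floor covers counting error only. Of 46934 gene identifiers, 46923 were matched by identifier to Ensembl release 115 of the WBcel235 assembly, from which names, gene types and coordinates were taken. Coordinates are therefore those of WBcel235 for the gene identifier and not those of the authors' alignment.

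Counts were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr, trimmed mean of M values (TMM) scaling, robust dispersion estimates and the quasi-likelihood F test on genotype, with Benjamini-Hochberg adjustment over the 9787 genes that passed the filter and a threshold of 0.05. CPM values are TMM-scaled, standard errors are on the log2 scale, and a positive log2 fold change means higher in the mutant. The common dispersion was 0.00305, a coefficient of variation of 5.52% between samples of a genotype. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, again with Benjamini-Hochberg adjustment over lists, and the estimated correlation and fry were run beside it. X linkage was tested with a two-sided Fisher's exact test over genes, which are not independent replicates, and with camera on the X-linked set. The share of counts on the X per library was compared with a two-sided exact permutation test, which with 3 against 3 samples cannot give a p below 0.10.

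The 21 gene lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took sin-3, the 8 largest changes in each direction, the 2 members of each list with the smallest p, and the 4 X-linked genes with the smallest p among those called higher. For the largest changes a gene had to be protein-coding, pass the threshold, have a mean of at least 5 CPM, carry a name of letters, hyphen and number, and have all values of one genotype above all of the other; the X-linked genes also had to be protein-coding and carry such a name. Members were matched by name to every identifier that carries it. Genes named outside the rule are said to be so. The values of 1 member of a list are not reported here.

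The pairs of libraries within each genotype were compared by a chi-square statistic of their counts over genes with at least 60 counts in all libraries together. It was 12.5 to 18.8 per degree of freedom within a genotype and 72.4 to 129.9 between genotypes, so no library is a copy of another. The steps were tested on simulated data drawn from the means, dispersions and library sizes of the comparison of the mutant with wild type, with known changes put into a small set of genes and 9591 genes tested. The edgeR test recovered 85.3% of genes lowered and 90.9% of genes raised by 1 on the log2 scale, 78.8% and 63.6% of those lowered and raised by 0.5, and made 8 false calls. Simulated X-linked genes with no shift gave a camera p of 0.869, and a shift of 0.5 gave an estimated median of 0.47. Genes were drawn independently, so the simulation does not show how camera behaves when genes are correlated.

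Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, protein-coding genes alone, the replicate number as a block and each library left out. The planned correction for GC content was not run because no genome sequence was used here; an offset for gene length was added after the data were seen, as were scaling on autosomal genes and a fit without X-linked genes.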

Results

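The germline transcriptome of adults lacking normal function of SIN-3, the scaffold protein of a histone deacetylase complex, was compared with that of wild-type animals. RNA was measured in distal gonad arms, with 3 wild-type and 3 sin-3(tm1276) libraries. Gene-assigned reads were 25002505, 24505604 and 24951839 in wild-type replicates 1 to 3 and 24491014, 30634455 and 26568423 in mutant replicates 1 to 3. The first axis of a multidimensional scaling of the libraries separated the genotypes. A read was assigned to 14874 ± 99.7 genes (SD, n = 3) in wild type and to 15898 ± 194 genes (SD, n = 3) in the mutant.

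The targeted gene sin-3 (WBGene00004117, chromosome I, 8416816 to 8425051 in WBcel235) was lower in every mutant library. Its level was 364.9 ± 5.71 CPM (SD, n = 3) in wild type and 179.7 ± 4.27 CPM (SD, n = 3) in the mutant, a log2 fold change of -1.02 ± 0.033 (SE) with an adjusted p of 2e-11 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. A gene-level count does not show which part of the transcript remains. Among the other listed subunits of SIN3 complexes, hda-1 and hda-2, which encode histone deacetylases, and the RbAp-like gene rba-1 fell, whereas hda-3, arid-1 and ing-3 rose. These subunits outside sin-3 and ing-3 are named because the counts were small, after their values were seen. The list thus held 3 higher, 4 lower and 3 uncalled genes of 10, with the same counts adjusted over the list alone. Its camera adjusted p was 0.553, and when libraries were scaled by their totals it held 6 higher and 1 lower gene and its median turned from -0.022 to 0.14, or to 0.026 when they were scaled on autosomal genes. The inhibitor of growth homologue ing-3 went from 59.7 ± 1.09 to 74.7 ± 1.06 CPM (SD, n = 3).

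Most genes measured in the distal gonad differed in level between the mutant and wild type, about evenly in both directions under TMM scaling. Of 9787 genes tested, 3065 were higher and 3003 lower in the mutant by the edgeR quasi-likelihood test, and 826 and 315 of these changed by more than 1 on the log2 scale. The neprilysin family peptidase gene nep-18 (chromosome II, 2557777 to 2564073) rose most among the genes the naming rule took, from 0.883 ± 0.060 to 9.63 ± 0.95 CPM (SD, n = 3), a 10.8-fold rise. The F-box genes fbxb-97 and fbxa-115 rose 6.12-fold and 4.32-fold, the ABC transporter gene pgp-2 rose 4.99-fold, and ttr-51, mct-4, best-15 and fkb-5 rose between 3.32-fold and 3.90-fold. The histone H2A gene his-16 (chromosome II, 13817760 to 13818143) was the most lowered of them, at 274.0 ± 28.2 CPM in wild type and 6.49 ± 0.90 CPM in the mutant (SD, n = 3), which is 42.3-fold lower. The gene sdc-3, whose product acts in dosage compensation and sex determination, went from 180.4 ± 3.81 to 24.4 ± 1.10 CPM (SD, n = 3), a log2 fold change of -2.89 ± 0.043 (SE). The zinc finger gene ztf-28, ogr-2, the thioredoxin gene trx-2 and gpcp-2 were 6.35-fold, 4.83-fold, 4.17-fold and 3.97-fold lower.

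The myosin heavy chain genes myo-1 and myo-2 also passed the rule, with log2 fold changes of -3.05 ± 0.61 and -2.77 ± 0.48 (SE), but their wild-type libraries were spread widely, at 13.2 ± 7.01 and 8.80 ± 4.54 CPM (SD, n = 3). The call of myo-1 ended, at adjusted p values of 0.0516 and 0.0539 in edgeR, without mutant replicate 1 and without mutant replicate 3. Of all tested genes 67.8% had values of one genotype above all of the other, where chance alone would give 10%. When libraries were scaled by their totals, all log2 fold changes moved up by a median of 0.17 and the split became 4446 higher and 1864 lower, and with the gene length offset, added after the data were seen, it became 2416 higher and 3715 lower. The genes sin-3, ttr-51, his-16, ztf-28, trx-2 and gpcp-2 overlap a gene on the other strand. Among genes named further on, so do pch-2, lag-1, mcm-4, fcd-2, hsp-90, skn-1, inx-9, deb-1 and syd-2. The gene his-16 also has close relatives among the other histone genes. Reads over several genes or with several alignments were kept out of gene counts, so these genes may have lost reads. The strand setting of the counting is not given, so how far their levels are affected is not known.

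**Figure D1:**
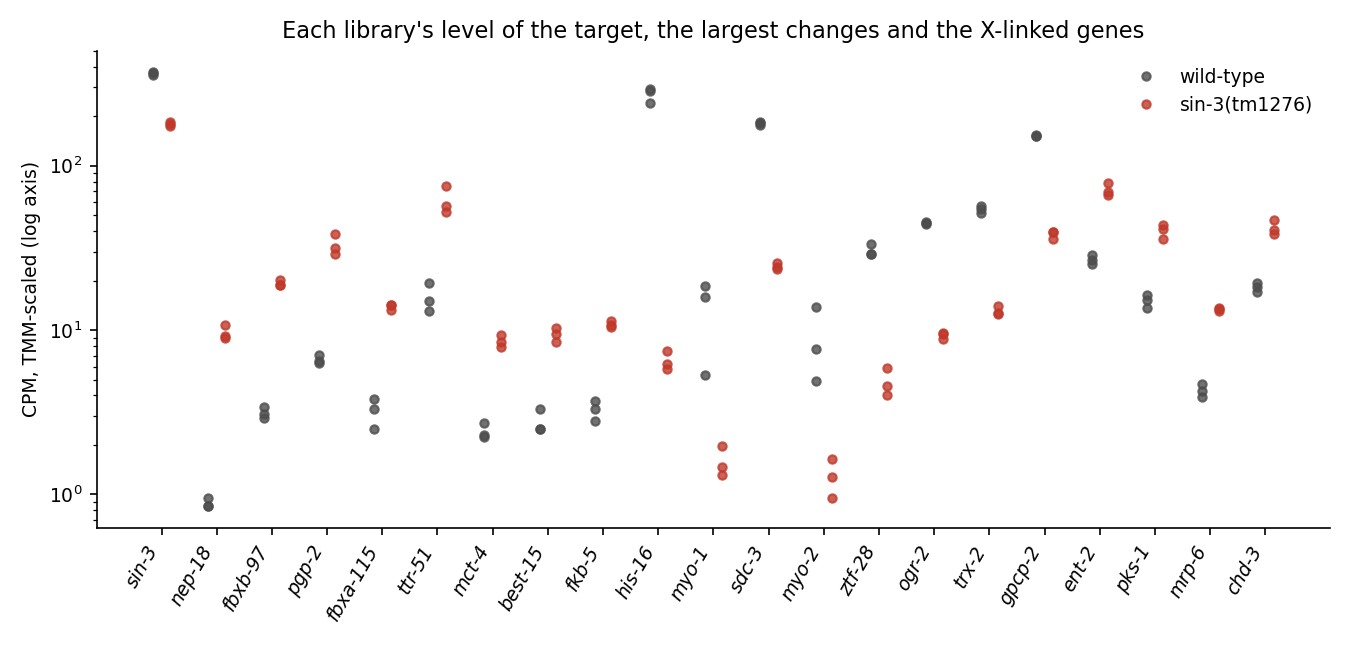
Level of sin-3, the 16 largest changes and the 4 X-linked genes of the naming rule in each library, in TMM-scaled CPM on a log axis, with 1 point per library and the genotypes in separate colours. For sin-3 the wild-type points lie near 364.9 CPM and the mutant points near 179.7 CPM, and the wild-type points of myo-1 and myo-2 spread more than those of the other genes.

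X-linked genes, most of which are kept at low levels in germ cells of the distal gonad, rose far more often than autosomal genes in the mutant. Of 1245 tested genes on the X, 766 were higher, 37 lower and 442 not called, while of 8522 autosomal genes 2285 were higher and 2966 lower. The median log2 fold change was 0.54 on the X and between -0.071 and -0.019 on the 5 autosomes. The nucleoside transporter gene ent-2 (X, 15601067 to 15603686) rose from 26.9 ± 1.71 to 71.3 ± 6.29 CPM and the Mi-2 chromatin remodeller gene chd-3 (X, 12846439 to 12852601) from 18.2 ± 1.14 to 41.9 ± 4.60 CPM (SD, n = 3). The polyketide synthase gene pks-1, which overlaps an antisense gene, and the ABC transporter gene mrp-6 rose 2.66-fold and 3.12-fold.

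The odds of being called higher were 4.36 times as large for X-linked as for autosomal genes (95% interval 3.85 to 4.95, two-sided Fisher's exact p = 3.4e-124), and the odds ratio for lower genes was 0.057 (0.040 to 0.080, p = 4.6e-155). Camera on the X-linked set gave p = 5.8e-13, and p = 0.037 with an estimated correlation. The share of nuclear protein-coding counts on the X was 1.29%, 1.24% and 1.22% in the wild-type libraries and 2.01%, 1.85% and 1.86% in the mutant libraries, a difference of 0.652 percentage points with an exact permutation p of 0.1, the smallest that 3 against 3 allows. X-linked protein-coding genes had the higher median at each level of expression, 0.68 against 0.35 for autosomal genes under 1 CPM, 0.59 against 0.28 at 1 to 8 CPM, 0.46 against -0.085 at 8 to 64 CPM and 0.48 against -0.12 at 64 CPM or more. The odds ratio for higher genes ranged from 2.41 with no filter to 10.3 among genes with a mean of at least 5 CPM, and that for lower genes from 0.020 among protein-coding genes of that level to 0.382 for changes over 1 on the log2 scale, and was 0.105 without wild-type replicate 1. Markers of the somatic gonad, described below with the other cell types, were mostly higher in the same libraries. Their median log2 fold change was 0.93 with the X-linked markers among them, and 0.62 for the autosomal markers.

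**Figure D2:**
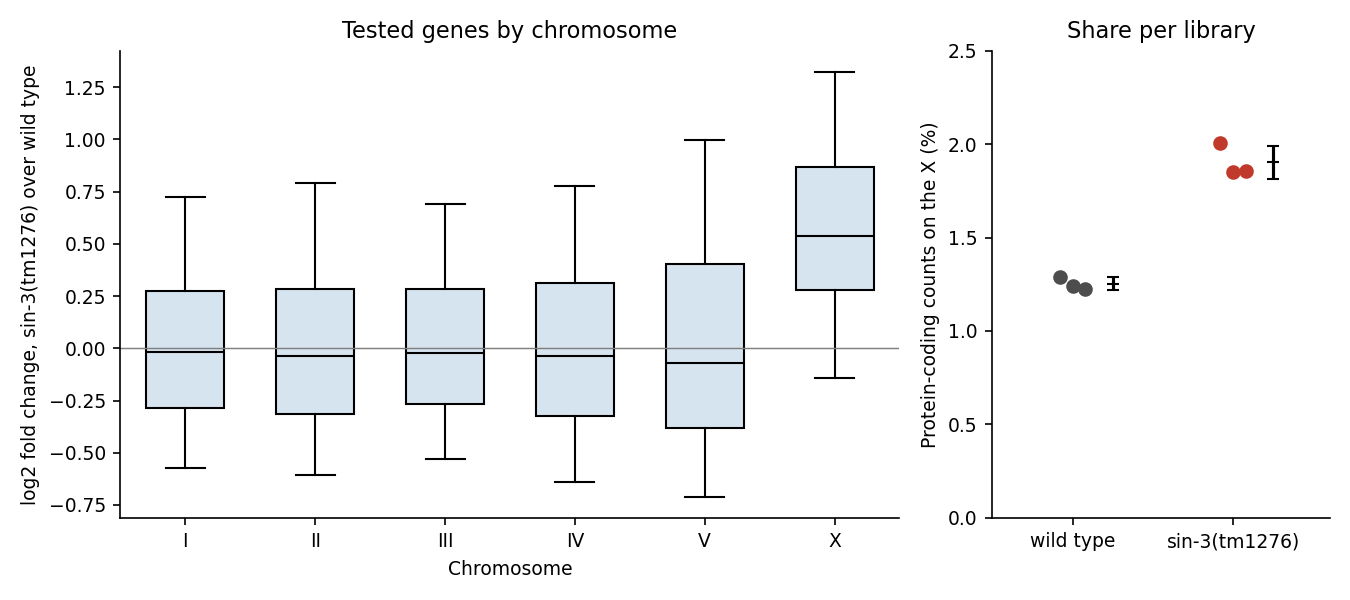
Left, log2 fold change of tested genes by chromosome, with the median, the quartiles as a box and whiskers to the 10th and 90th percentiles; right, the percentage of protein-coding counts on the X in each library, with mean and SD beside the points. The X median is 0.54, and the mutant libraries lie at 1.85% to 2.01% against 1.22% to 1.29% in wild type.

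**Figure D3:**
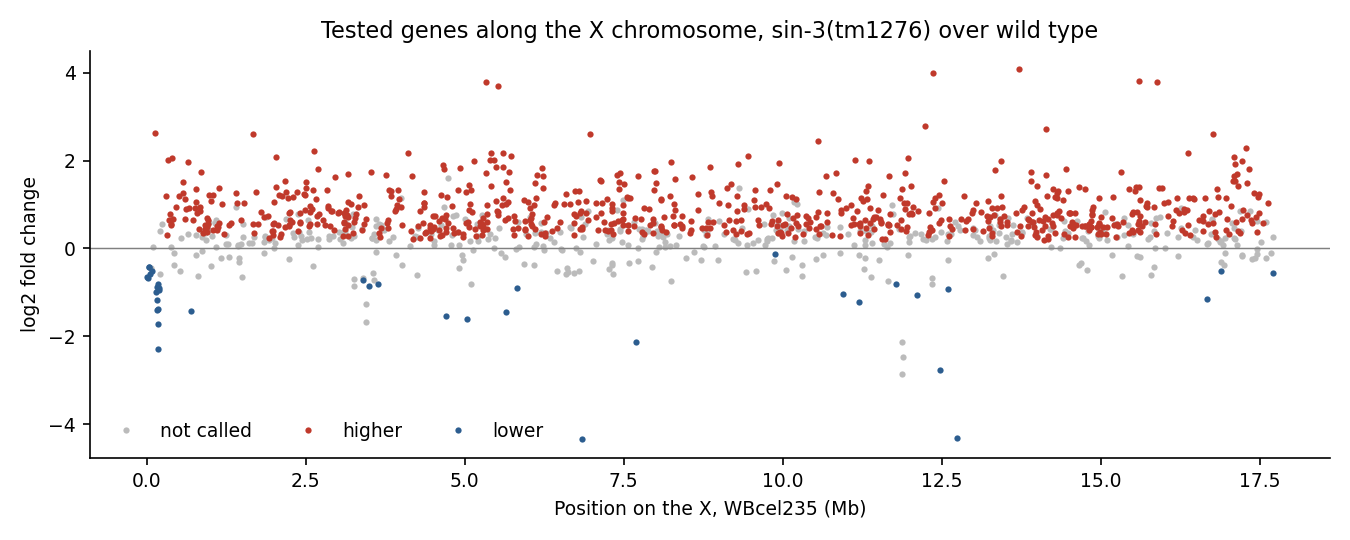
Log2 fold change of the 1245 tested X-linked genes against their start position in WBcel235, in megabases. Of these genes 766 are higher and 37 lower, and 16 of the lower genes start in the first 200000 bases.

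Genes of oocyte production, meiosis and DNA replication were more often lower than higher in the mutant under TMM scaling, by modest amounts. Autosomal protein-coding genes in general had median log2 fold changes of -0.085 at 8 to 64 CPM and -0.12 at 64 CPM or more. Somatic gonad markers in the same libraries had a median of 0.93, or 0.62 for the autosomal ones. Of 38 oogenesis genes, 26 fell and 3 rose. The Y-box RNA-binding protein gene cey-2 went from 2340 ± 54.3 to 1500 ± 21.6 CPM and mex-6, an embryonic polarity gene, from 261.5 ± 8.23 to 169.5 ± 4.35 CPM (SD, n = 3). The 3 that rose, named after their values were seen, were mex-3 and the eggshell layer genes perm-2 and perm-4. Of 50 meiotic chromosome genes, 30 fell and 8 rose, among them the checkpoint ATPase gene pch-2, with a log2 fold change of -1.50 ± 0.061 (SE), and skr-1, at -0.97 ± 0.039 (SE). Of 38 DNA replication genes, 24 fell and 6 rose, with the helicase subunit gene mcm-4 at -0.66 ± 0.033 and the ligase gene lig-1 at -0.58 ± 0.033 (SE). Of 21 genes of the DNA damage response and apoptosis, 11 fell and 0 rose, among them the checkpoint kinase gene chk-1 at -0.73 ± 0.041 and fcd-2 at -0.52 ± 0.033 (SE). Adjusted over the list alone, the lower genes numbered 26, 31, 26 and 11 in these lists.

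These lists had median log2 fold changes of -0.26, -0.20, -0.23 and -0.15 and camera adjusted p values of 1.6e-04, 1.2e-04, 4.3e-04 and 0.0078. With an estimated correlation none was called, at adjusted p = 0.533, 0.409, 0.351 and 0.221. Under scaling by library totals the oogenesis list held 9 higher and 18 lower genes, the meiotic list 17 and 20, the replication list 13 and 16 and the DNA damage list 6 and 7. The first 3 medians were then -0.098, -0.032 and -0.065, and the last turned to 0.020, where the DNA damage list lost its camera call (adjusted p = 0.104). Among genes with a mean of at least 5 CPM the replication and DNA damage lists lost their calls (adjusted p = 0.0544 and 0.140).

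Of 50 genes of P granules and small RNA pathways, 30 fell, 8 rose and 12 were not called, with the same counts adjusted over the list alone. Under scaling by library totals 19 fell and 15 rose. Without its 5 X-linked genes the list had a median log2 fold change of -0.22. In the fit without X-linked genes 28 fell and 4 rose, of 45 tested. In the same libraries 15 of 21 somatic gonad markers were called higher, with a median log2 fold change of 0.93, or 0.62 for the autosomal ones. Autosomal protein-coding genes in general had medians of -0.085 at 8 to 64 CPM and -0.12 at 64 CPM or more. The piRNA factor gene tofu-2 went from 121.2 ± 3.19 to 76.3 ± 0.89 CPM, whereas the Argonaute gene vsra-1 went from 46.5 ± 2.18 to 106.6 ± 1.31 CPM (SD, n = 3). The list median was -0.18, or -0.017 under scaling by library totals, with a camera adjusted p of 0.0078, and adjusted p = 0.492 with an estimated correlation. The call ended under that scaling (adjusted p = 0.208) and among genes with a mean of at least 5 CPM (adjusted p = 0.238). Among 17 regulators of germline stem cells 7 fell and 4 rose, or 8 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.498). The Notch pathway target lst-1 and the Notch effector gene lag-1 had log2 fold changes of -0.45 ± 0.042 and -0.32 ± 0.037 (SE), and under scaling by library totals 6 genes of the list were higher and 3 lower and its median turned from -0.11 to 0.056.

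Genes of sex determination and sperm formation included several of the larger decreases. Of 16 sex determination genes, 8 fell and 4 rose, led by sdc-3 and by fem-3, a gene that promotes male fate, at 83.9 ± 5.49 CPM in wild type and 45.4 ± 2.54 CPM in the mutant (SD, n = 3). Of 43 spermatogenesis genes in the files 10 were tested, of which 5 fell and 1 rose. The cytoplasmic polyadenylation factor gene cpb-1 fell from 51.8 ± 1.16 to 15.1 ± 1.02 CPM and the sperm gene regulator spe-44 from 28.1 ± 1.67 to 12.0 ± 0.92 CPM (SD, n = 3). None of 31 major sperm protein genes was tested, since none had more than 6 counts in a library. Both tested lists were called by camera (adjusted p = 9.1e-04 and 0.0078) and neither was with an estimated correlation (adjusted p = 0.221 for both). Their counts adjusted over the list alone were the same as over all genes. Their medians were -0.12 and -0.34. Without its 3 X-linked genes the first list had a median of -0.24, and in the fit without X-linked genes 8 fell and 2 rose, of 13 tested. Under scaling by library totals the first turned to 0.045, with 4 genes higher and 6 lower, and the second was -0.17, with 3 higher and 5 lower. With single libraries left out the spermatogenesis median ranged from -0.14, without wild-type replicate 1, to -0.36, without mutant replicate 2. In these libraries too 15 of 21 somatic gonad markers were called higher, with a median log2 fold change of 0.93, or 0.62 for the autosomal ones. With no filter 38 spermatogenesis genes were tested, at a median of 0.60 and a camera adjusted p of 0.268.

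Ribosomal protein genes were mostly lower in the mutant. In the same libraries somatic gonad markers had a median log2 fold change of 0.93, or 0.62 for the autosomal ones. Autosomal protein-coding genes at 64 CPM or more had a median of -0.12. Of 77 tested, 72 were lower and 4 higher, over all genes and adjusted over the list alone, with a median log2 fold change of -0.35 that was -0.19 under scaling by library totals. The small subunit gene rps-8 went from 2723 ± 80.2 to 1773 ± 32.7 CPM, and rpl-41.1 from 86.0 ± 7.26 to 281.6 ± 10.4 CPM (SD, n = 3). The other genes that rose, named after their values were seen, were rpl-24.2, rpl-11.2 and rpl-25.1, and the latter 2 are X-linked. Camera gave an adjusted p of 3.6e-12, and adjusted p = 0.221 with an estimated correlation. Ribosomal protein and histone genes have close copies, so counts of single members are uncertain.

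Histone genes divided. Of 32 tested, 15 rose and 11 fell, or 18 and 11 adjusted over the list alone. The neighbouring genes his-61 and his-59 on chromosome IV had log2 fold changes of -0.88 ± 0.036 and -0.86 ± 0.037 (SE). The list's median was 0.22, its mean was -0.036 because of his-16, and camera did not call it (adjusted p = 0.416, direction down). Of 44 genes of chromatin repression and histone methylation, 11 rose and 18 fell, with the same counts adjusted over the list alone. The X-linked synMuv B gene lin-15B rose from 42.5 ± 0.69 to 86.8 ± 4.94 CPM and the MTA homologue egl-27 fell from 163.6 ± 3.41 to 115.1 ± 2.53 CPM (SD, n = 3); lin-15B overlaps another gene on its strand. The median of this list was -0.0045, its mean 0.032 and its camera adjusted p 0.733. Under scaling by library totals 23 genes were higher and 11 lower, at a median of 0.16. Without its 7 X-linked genes the main fit's median was -0.092, and in the fit without X-linked genes 10 rose and 16 fell, of 37 tested.

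Stress and energy genes moved in both directions. Of 20 heat shock and stress genes, 7 fell and 5 rose. Without wild-type replicate 1, 11 fell and 5 rose, at a median of -0.22, and without wild-type replicate 3 the median was -0.074. The chaperone gene hsp-90 went from 5849 ± 218.7 to 3840 ± 69.8 CPM and the stress regulator gene skn-1 from 144.1 ± 8.92 to 212.7 ± 6.38 CPM (SD, n = 3). Of 15 mitochondrial stress genes, 5 rose and 3 fell, with the protease gene ymel-1 at a log2 fold change of 0.52 ± 0.036 and the chaperone gene hsp-6 at 0.44 ± 0.035 (SE). Of 36 nuclear genes of oxidative phosphorylation, 15 rose and 15 fell, with the cytochrome oxidase subunit genes cox-6A and cox-7C at 0.73 ± 0.041 and -0.76 ± 0.046 (SE). Adjusted over the list alone these counts were the same. Camera called none of these 3 lists (adjusted p = 0.733, 0.416 and 0.910), whose medians were -0.16, -0.0057 and -0.020 and turned to 0.0022, 0.16 and 0.15 under scaling by library totals, where 8, 8 and 20 genes were higher and 6, 1 and 11 lower. The means of the latter 2 were 0.018 and 0.015, and the camera direction was up for mitochondrial stress and down for oxidative phosphorylation. Without its 6 X-linked genes the oxidative phosphorylation list had a median of -0.14. In the fit without X-linked genes 9 of its genes rose and 15 fell, of 30 tested.

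Markers of the gonadal sheath and somatic gonad were mostly higher in the mutant, while the muscle, intestine, hypodermis and neuron lists were not called. Of 21 tested somatic gonad markers, 15 rose and 0 fell, with the same counts adjusted over the list alone. The median log2 fold change was 0.93, or 0.62 without the 5 X-linked markers. The collagen IV gene emb-9 had a log2 fold change of 1.25 ± 0.042 (SE) and the sheath innexin gene inx-9 went from 12.6 ± 1.14 to 31.2 ± 3.21 CPM (SD, n = 3). The filamin gene fln-1, named after its value was seen, was not called, at 1621 ± 140.6 CPM in wild type and 1597 ± 44.6 CPM in the mutant (SD, n = 3). The summed level of all listed somatic gonad markers was 2363 ± 157.4 CPM in wild type and 2675 ± 78.5 CPM in the mutant (SD, n = 3; exact permutation p = 0.1). Camera gave this list an adjusted p of 6.0e-06, and adjusted p = 0.221 with an estimated correlation.

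Of 25 muscle markers 3 rose and 3 fell, of 23 intestine markers 1 rose and 1 fell, and of 13 hypodermis markers 2 rose and 3 fell. Examples that passed the test were the muscle genes deb-1, with a log2 fold change of 0.92 ± 0.088, and tnt-4, at -3.36 ± 0.47 (SE). Others were the intestinal protease gene cpr-5 at -3.73 ± 0.59, and the hypodermis genes cuti-1 at 1.82 ± 0.35 and lin-26 at 0.17 ± 0.044 (SE). Levels of tnt-4 were 1.24 ± 0.49 CPM in wild type and 0.119 ± 0.049 CPM in the mutant (SD, n = 3), the latter near the floor. Those of cuti-1 were low too, at 0.313 ± 0.063 and 1.12 ± 0.32 CPM. The wild-type libraries of cpr-5 were spread widely, at 8.94 ± 4.91 CPM, against 0.669 ± 0.098 CPM in the mutant (SD, n = 3). The intestinal filament gene ifb-2, at 0.71 ± 0.29 (SE), was called at an edgeR adjusted p of 0.0453 and lost the call under 8 alternatives. Of 17 neuron markers 7 rose and 4 fell, with syd-2 on the X at 0.83 ± 0.12 and snb-1 at -0.63 ± 0.048 (SE). With DESeq2 4 rose and 4 fell. In the fit without X-linked genes 4 rose and 4 fell, of 13 tested, and without its 4 X-linked genes the neuron list's main median was 0.16. Without wild-type replicate 2 the neuron counts were 4 and 3, and without mutant replicate 3 they were 6 and 2. Adjusted over the list alone, 2 and 3 muscle, 0 and 1 intestine, 2 and 3 hypodermis and 7 and 4 neuron genes were higher and lower. Camera adjusted p values were 0.910, 0.733, 0.733 and 0.733 for medians of -0.12, -0.51, -0.69 and 0.34, and for muscle the camera direction, up, was opposite to the median, which turned to 0.050 under scaling by library totals. Wild-type replicate 1 held less of the muscle, intestine and hypodermis markers than the other wild-type libraries, with a summed level of 1175 CPM against 1901 and 2215 CPM, and the mutant libraries held 1521, 1267 and 1184 CPM. Without wild-type replicate 1 the intestine and hypodermis lists were called lower, at camera adjusted p values of 0.0417 and 0.00518. The higher and lower genes were then 2 and 9 of 25 for muscle, 0 and 13 of 24 for intestine and 2 and 9 of 13 for hypodermis. The histone list was then called with direction down at a camera adjusted p of 0.0417, while its median stayed positive at 0.21.

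**Figure D4:**
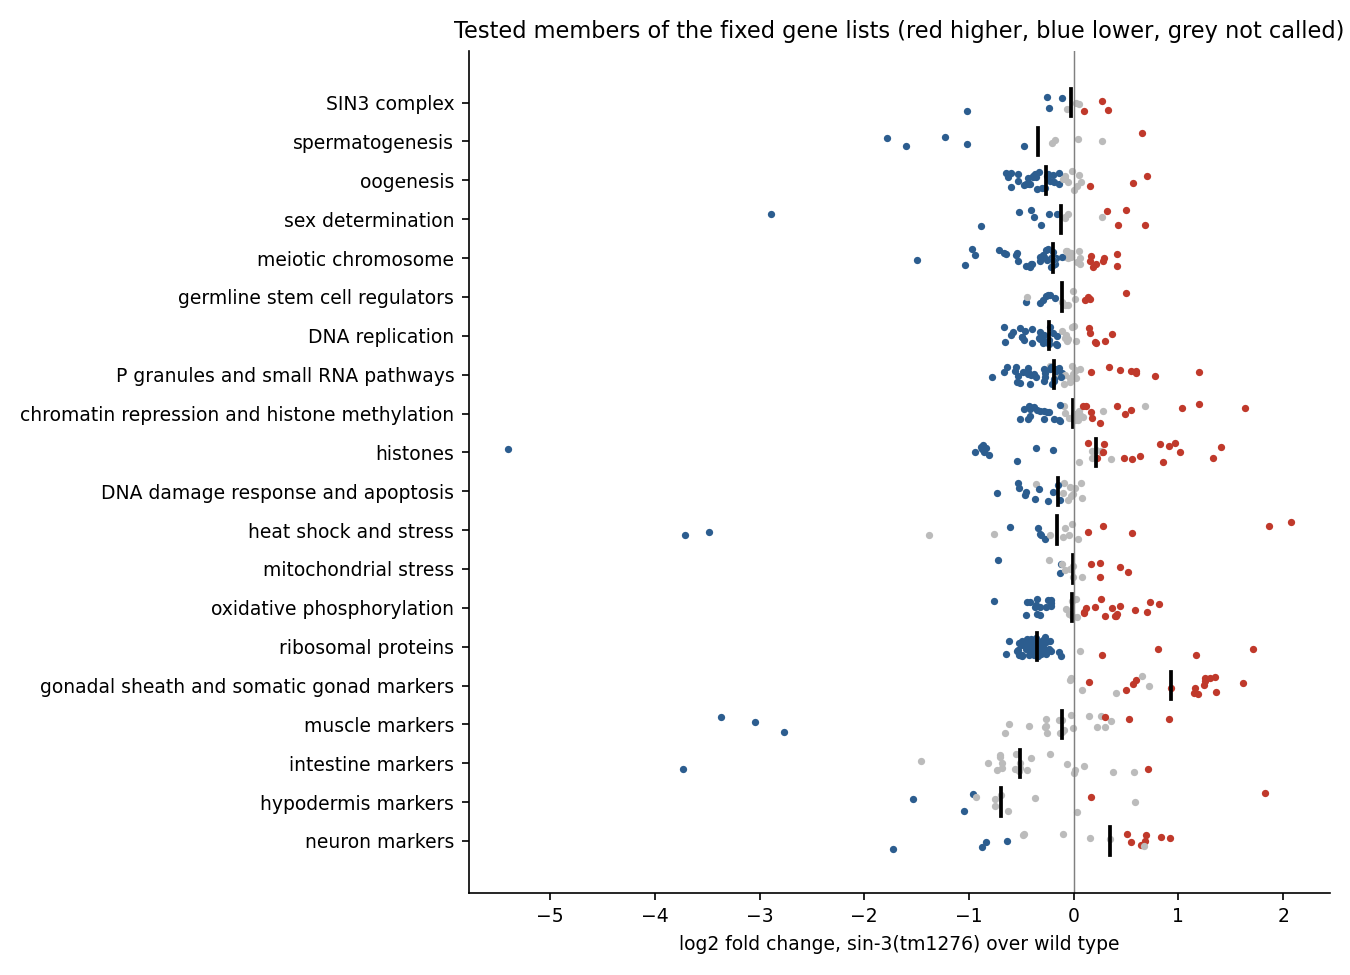
Log2 fold change of each tested member of the gene lists, 1 point per gene, with a black bar at the list's median and colours for genes called higher, called lower or not called. Ribosomal protein genes gather around a median of -0.35, which was -0.19 under scaling by library totals, and somatic gonad markers around 0.93.

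The authors' deposited table of the same comparison held 14805 genes, of which 2573 were higher and 3185 lower at an adjusted p under 0.05. The edgeR calls shared 2445 of the higher and 2945 of the lower genes with it, and 0 genes were called in opposite directions. Across the 9787 genes in both, which are not independent replicates, the log2 fold changes had a Pearson r of 0.978. For sin-3 the authors' deposited table gives -1.05 ± 0.036 (SE), for sdc-3 and his-16 values that share the sign of the edgeR estimates, and for nep-18 a log2 fold change of 3.38.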

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

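The share of reads that overlapped more than one gene and were therefore assigned to none, which enters none of the comparisons, was higher in each mutant library than in any wild-type library. It was 0.470% ± 0.0045 in the mutant and 0.446% ± 0.0079 in wild type (SD, n = 3), with an exact permutation p of 0.1, the smallest that 3 against 3 allows. No biological explanation was tested. The share of reads with several alignments, in contrast, was 5.70% ± 0.23 in the mutant and 7.39% ± 0.62 in wild type (SD, n = 3; exact permutation p = 0.1).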

How the results depend on the processing

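Scaling on autosomal genes, the fit without X-linked genes and the gene length offset were chosen after seeing the data; the planned GC correction was not run, alone or with the block. Under scaling by library totals 1864 genes were lower, and a shift of all genes by a median of 0.17 goes with it. Camera with an estimated correlation called 0 lists and fry, which compares no list with other genes, 14. Lists that were not called in either setting changed the direction of the camera test as follows, given with their median, which need not share that direction. Scaling by totals gave 0.14 for the SIN3 complex, 0.16 for chromatin, 0.15 for oxidative phosphorylation, 0.050 for muscle and 0.51 for neuron; the minimum of 5 CPM gave 0.043 for chromatin and 0.048 for oxidative phosphorylation. Muscle was at -0.11 with no filter, -0.098 with the replicate block, -0.19 with block and length offset, -0.067 with autosomal scaling and -0.12 with fry. The length offset gave -0.62 for intestine, autosomal scaling 0.028 for oxidative phosphorylation, and the fit without X-linked genes 0.21 for neuron. Without single libraries the medians ranged from -0.34 to 0.057 for muscle, from -0.76 to -0.24 for intestine and from -0.057 to 0.0069 for oxidative phosphorylation, whose test also turned at -0.0045. Apart from the shift by totals, the cause was not tested. No named gene reversed: 1038 comparisons of a named gene with an alternative stayed as they were and 12 lost the call. With 1 library left out at a time 2682 to 3027 genes were higher, 2865 to 3004 lower, and 9 to 12 lists were called. The replicate block gave 2906 and 2935 genes. Same-numbered samples correlated at -0.25, -0.068 and -0.10 in their deviations, so no effect shared by equal numbers was seen. With 3 samples per genotype these values cannot exclude a shared day or culture. Depth limits genes near the floor of 0.0942 to 0.130 CPM.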

Other observations

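The gene families, the window scan and the mitochondrial genes below, and the tests of explanations for the X-linked rise, for the left end of the X, and of body tissue RNA and cell share for the somatic gonad markers, were chosen after the results were seen. Of 19 tested genes of the mitochondrial genome 14 were higher in the mutant. Of 12 protein-coding mitochondrial genes tested, 10 were higher in the mutant and 0 lower by edgeR, with a median log2 fold change of 1.15; ND1 and ND6 rose by 1.17 ± 0.051 and 1.29 ± 0.052 and COX3 by 1.08 ± 0.15 (SE). The 2 mitochondrial rRNA genes were at -0.033 and 0.14, neither called, in libraries depleted of rRNA, and 4 of 5 tested mitochondrial tRNA genes were higher. Among 107 families of genes that share a name stem and have at least 8 tested members, 7 were called by camera with the preset correlation and none of these 7 with an estimated correlation (adjusted p = 0.894 or 0.923). Those called down were rps (0 higher and 31 lower), rpl (4 and 39), ints (0 and 10) and him (2 and 7). The family mrp was called up (5 and 2), with 6 of its 8 members X-linked. The rps and rpl genes belong to the ribosomal protein list above. The medians of ints and him were -0.31 and -0.22. Families were tested under TMM scaling alone, and scaling by library totals moved log2 fold changes up by a median of 0.17. The nuclear hormone receptor genes (nhr, 97 tested) held 54 higher and 3 lower genes at a median of 0.54, or 0.53 for the autosomal members, and the F-box genes fbxb (11 tested) held 7 higher and 0 lower at a median of 1.16. In the same libraries somatic gonad markers had a median of 0.93, or 0.62 for the autosomal ones. Autosomal protein-coding genes under 1 CPM and at 1 to 8 CPM had medians of 0.35 and 0.28. The adjusted p values of nhr and fbxb with the preset correlation were 0.0126 and 0.00893.

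With 3 against 3 samples only 10 splits exist, too few for a share under 0.05. The real split gave 3065 higher and 3003 lower genes. The highest count in either direction among the other splits was 0, so 1 split, the real one, was as large. Every other split puts both genotypes into each group, so the genotype difference adds to the spread within groups. Calls of 0 there are therefore no measure of chance. With 0 genes called, the other splits could show no excess or deficit of X-linked genes, so they say nothing further about the X. For gene lists 4 of the 10 splits, the real one included, called at least the real number of 9, and the highest other split called 11. The mixed splits still carry part of the genotype difference, so their list calls do not show how often lists are called by chance. The splits therefore cannot say whether a camera call with the preset correlation sets a list of these libraries apart.

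X-linked genes were higher in the mutant. Their low level in wild type argues little: among 10000 autosomal lists matched on mean expression the highest median log2 fold change was 0.25, against 0.54 for the 1177 X-linked protein-coding genes. Body tissue carried along in dissection would need its markers to rise by the 1.45-fold median of X-linked genes, but the mutant library with most muscle, intestine and hypodermis RNA reached 0.863 of the wild-type mean. RNA of somatic gonad cells stays open, because autosomal somatic gonad markers had a median of 0.62 and the design ties it to genotype. On the summed measure used for body tissue, these markers went from 2363 ± 157.4 CPM in wild type to 2675 ± 78.5 CPM in the mutant (SD, n = 3). That sum also rose less than 1.45-fold, but most of it is fln-1, which was not called, so the sum does not decide. The hypothesis that normal sin-3 keeps X-linked genes low in germ cells may hold and was not tested apart from somatic gonad RNA.

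The left end of the X ran against the rest of that chromosome. Of 442 windows of 200000 bases with at least 10 tested genes, the first window of the X lay lowest relative to its chromosome's median. Of its 19 genes, among them tmed-12 and chkr-1, 16 were lower and 1 higher, at a median of -0.80. Loss of the region from both chromosome copies would leave almost no reads, but a median of 57.4% of the wild-type level was left. Reads shared with near-identical copies could contribute, as 11 of the 19 are pseudogenes. The fall was not confined to these, with a median of -0.67 for the pseudogenes and -0.88 for the 8 protein-coding genes. The latter median lay below -0.071, the 10% quantile of X-linked protein-coding genes, which argues against a fall of pseudogenes alone. Shared reads cannot be told apart without sequence from a regional change or a strain variant.

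Somatic gonad markers were mostly higher in the mutant. Among 10000 autosomal lists matched on mean expression, the median of the list medians was -0.014 and their middle 95% ended at 0.27. The 16 autosomal markers, at a median of 0.62, lay above that range, which argues against expression level alone for these markers. They did not lie above the highest list median, 0.68, the bound set in advance, so that bound does not exclude expression level. Body tissue again reached at most 0.863 of the wild-type mean, where 1.90-fold, the median over all tested markers with the X-linked ones, was needed. A larger share of somatic gonad cells may contribute, and it cannot be told apart from a change within cells, because the members ranged from -0.037 to 1.62 and germ cells may supply part of the flat ones. Whether the genotype acts on these genes within germ cells was not tested.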
